A study of Mus musculus with 4 samples.

How the data were processed

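The samples were back skin biopsies of 10-day-old mice, 2 with keratinocyte-specific deletion of Adam17 (cKO) and 2 Cre-negative controls. Per the labels, replicate 1 of each group came from litter 1 and replicate 2 from litter 2, so the replicate numbers pair the animals. Per the labels' protocols, RNA was purified with a kit for fibrous tissue including a DNase step, 500 ng was labelled with Cy3 by a 1-colour kit, and the arrays were the Agilent whole mouse genome design, numbered 014868 in the file headers with probe positions in mm9. The submitters' processing notes name Agilent Feature Extraction 10.5, while the file headers give version 10.7.3.1. All 4 arrays lay on 1 slide and shared 1 scan time per the file headers, so slide and scan could not be tested as batches. The dates of sampling, RNA preparation and labelling are not given in the sources used here.

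The deposited scanner files give, per spot, the authors' intensity values, of which the background-subtracted and detrended processed signal was used (the mean signal and local background served for 1 alternative). The flags for outliers and for signal well above background came from the same files. The authors' series table holds log2 values. Set against the scanner values, it equalled the log2 processed signal minus the array's 75th percentile and minus each probe's median over the arrays (correlation at least 0.99999, slope close to 1, column medians of -0.08, 0.06, -0.06 and 0.08 for control replicates 1 and 2 and cKO replicates 1 and 2). It was used as an alternative.

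For the main result, log2 of the processed signal minus each array's 75th percentile over gene spots was taken. Control spots and spots flagged as non-uniform or population outliers (51 to 66 per array) were left out, and spots of one probe were averaged. A probe needed a value on all 4 arrays and had to be well above background on both arrays of at least 1 group, which 22190 of 41174 probes met. Each gene was represented by its probe with the highest mean over the 4 arrays, which gave 15552 genes, 5096 of them with several probes. Of the 10 genes past the threshold with several probes, 1 (Gprc5c) had another probe with the opposite sign, and Npr2 had 2 other probes near 0. Gene names came from the accession in the files for 26690 probes, matched without versions to RefSeq genes of assembly GRCm38.p6, from a current symbol for 5189 and from a synonym for 952. The other 8343 kept the name in the files. Coordinates are those of the files in mm9, for which no exon annotation was used here.

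Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 4 arrays, two-sided, no covariate, Benjamini-Hochberg over all genes, threshold 0.05). The prior added 2.37 degrees of freedom to the 2 residual ones. The median difference over all genes was 0.03 and the median standard error 0.11 on the log2 scale. The litter pairing was checked with the deviations from the group means, which correlated across genes at 0.35 between the groups (Spearman 0.43). As the design text names matched pairs but no statistical model, litter as a block was an alternative. Where a gene was not well above background on either array of a group, the text gives a lower limit of the fold. It is the mean of the brighter group against the mean, in the other, of the higher of the probe's own signal and the lowest signal among probes well above background on that array.

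The groups of genes were 38 lists, fixed with all planned choices before the data were examined. They were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry. Members were matched by symbol or listed alias, and 43 of the 653 listed genes stood in more than 1 list. Setting members below background to their limits moved no list's median by more than 0.031. The named genes were Adam17, the 12 largest rises and the 12 largest falls among genes past the threshold that changed the same way in both litters. Genes known only by clone or accession names and members of the sex-linked list were passed over (other genes on the X chromosome were not), and only 7 rises qualified. Of each list, up to 4 members past the threshold were named or, if none passed, the 2 with the smallest p as values only. One gene that the rule would name is not reported here. Names outside this rule were chosen after their values were seen.

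The test was checked on simulated data for the comparison of 2 against 2 arrays over 15552 genes, with 200 changed genes and 20 simulations. It recovered 44.6% of genes changed 2-fold and 89.2% of those changed 4-fold, with 5.0% false calls among those called and on average 0.15 calls with no change. Lists shifted by 0.4 on the log2 scale were recovered in 100% of cases with the preset correlation and in 0% with an estimated one. The latter thus had no power at this size. The spread of the simulated genes was drawn from the prior that limma fitted to these arrays, with normal errors and no dependence on intensity. The rate of false calls thus follows from the test's own model and does not measure that rate on the real arrays. The simulated genes varied independently and without a litter effect, so the check does not cover lists whose genes vary together. On the real arrays the estimated correlation was -0.01 in the hair shaft list and 0.64 in the skeletal muscle list. It was 0.82 in the sex-linked, 0.33 in the tight and gap junction, 0.32 in the red cell, 0.13 in the T cell and 0.12 in the inner root sheath list. In the other lists that passed with the preset value it lay between -0.02 and 0.05. Where the genes of a list vary together by more than the preset 0.01, the preset test's p may be too small. The p-values rest on the spread between 2 animals per group, combined with a prior from all genes (2.37 degrees of freedom against 2). The 2 animals of a group came from different litters, and the cKO pair also differed in its sex-linked signals, so that spread includes these differences.

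Alternatives were quantile normalization, median centring, limma's normexp background correction with an offset of 50, the authors' log2 table, other filters on dim probes, flagged spots kept, probes averaged, an intensity trend or robust prior, the litter block, each array left out, other thresholds, every probe by itself and other list tests. A slide block could not be fitted with 1 slide. In 3 spots of cKO replicate 2 the local background exceeded the spot's signal, with a lowest difference of -27527.5 intensity units. These 3 spots moved the background mean that normexp fitted for that array to -390, against 38.4 to 44.7 on the other arrays and 47.9 without them. A fit without such spots was therefore added after the data were examined, as was the fit without the X and Y chromosomes.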

Results

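Gene expression was measured in back skin of 10-day-old mice that lacked ADAM17 in keratinocytes. ADAM17 is a membrane-bound metalloprotease that releases many surface proteins, among them ligands of the EGF receptor. The gene carried loxP sites on both alleles and was deleted by Cre recombinase under the keratin 14 promoter, which is active in the basal layer of the epidermis and in the outer cells of the hair follicle. The series held 2 knockout animals (called cKO, for conditional knockout) and 2 Cre-negative control littermates, as 1 control and 1 cKO animal from each of 2 litters, on a mixed background of 129Sv and C57BL/6. RNA from each biopsy was hybridised to 1 array of a single slide with 4 arrays, a 1-colour Agilent whole mouse genome design. Between 53.7% and 56.6% of the 43379 gene spots per array were well above background, none was saturated, and the 75th percentile of the signal lay between 751 and 784. Log2 signals correlated across probes at 0.994 between the controls and 0.992 between the cKO arrays, and at 0.990 and 0.988 between littermates of different genotype. Probes are not independent replicates, and the number of arrays limits the precision of every value. All differences below are cKO minus control, on log2 signals relative to each array's 75th percentile, over 15552 genes.

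Adam17 itself was read by 2 probes on chromosome 12 (mm9), at 21330545 to 21330604 and at 21330653 to 21330712. The gene's signal was 0.40 ± 0.05 (SD, n = 2) in control skin and -0.13 ± 0.01 (SD, n = 2) in cKO skin, a difference of -0.54 ± 0.09 (SE). The cKO level was thus 69.0% of control with this probe and 68.5% with the other. The signal was lower in both litters, by -0.58 and -0.49, but the difference did not pass the test over all genes (adjusted p = 0.114, limma; 0.111 with the replicate block, that is, with litter in the model). Whole skin also holds cells in which the keratin 14 promoter is not active. Which exon was removed is not given in the sources used here, so a probe outside it would not check the deletion.

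The comparison of cKO with control skin asks which transcripts of the skin differ when ADAM17 is deleted in keratinocytes. As the controls lacked Cre, an effect of Cre itself cannot be told apart from the loss of ADAM17. Between the genotypes, 53 genes passed an adjusted p of 0.05, 11 of them higher and 42 lower in cKO skin. Every one of the 53 differed in the same direction in both litters and by at least 2-fold in the fitted values. With 2 arrays per group a gene had to differ by many standard errors to pass. This all but fixes both properties in advance, so they are not separate evidence. The falls included Plb1 (phospholipase B), Csn3 (kappa casein), Fxyd4 (a regulator of the sodium pump) and the growth factor gene Fgf5, which is known to end the growth phase of the hair cycle. The rises included Agt, which encodes angiotensinogen, and Slc5a1, a sodium-dependent glucose transporter. The calls rest on all 4 arrays and on the model without litter. With litter as a replicate block, 0 genes passed in limma (lowest adjusted p = 0.0567), while 3706 had an unadjusted p under 0.05, against 2512 without the block. The count was also 0 without control replicate 1 and without control replicate 2, 38 without cKO replicate 1 (21 of them among the 53), 24 without cKO replicate 2 (17 among the 53) and 0 without the filter on dim probes.

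**Figure D1:**
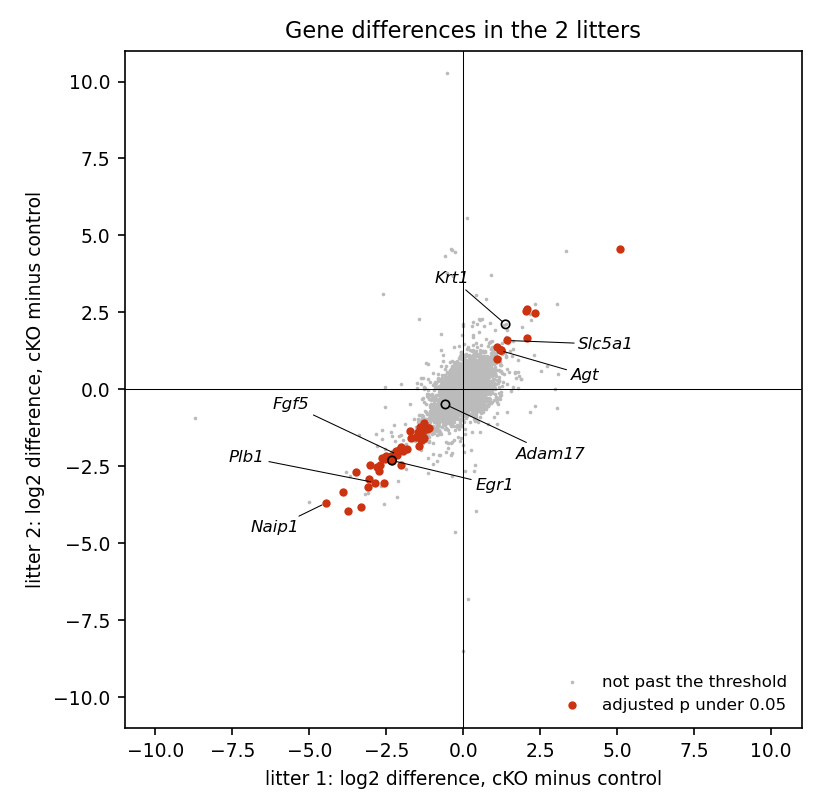
Each point is a gene, with the log2 difference between cKO and control skin in litter 1 on the horizontal axis and in litter 2 on the vertical axis; red points are the 53 genes with an adjusted p under 0.05. All red points lie in the lower left (42 genes lower in cKO skin) or the upper right (11 genes higher), which the threshold itself brings about. The labelled open circles Adam17, Egr1 and Krt1 did not pass the threshold.

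Among the genes that fell, Plb1 (chromosome 5, 32666473 to 32666532, mm9) went from 1.95 ± 0.02 to -1.01 ± 0.09 (SD, n = 2 each), a 7.75-fold lower signal (adjusted p = 0.0121). Its second probe gave a log2 difference of -3.20. Csn3 was 7.93-fold lower (adjusted p = 0.0121) and Fxyd4 6.99-fold lower (adjusted p = 0.0214). Fgf5 (chromosome 5, 98705980 to 98706039) went from 2.08 ± 0.06 to -0.05 ± 0.07 (SD, n = 2 each), a 4.38-fold fall that measured -2.14 in litter 1 and -2.12 in litter 2 (adjusted p = 0.0188). H2al1m, a histone H2A variant gene best known from the testis, was 8.75-fold lower (adjusted p = 0.0148). Ovgp1, which encodes oviductal glycoprotein, was 6.48-fold lower (adjusted p = 0.0324), with 1 of the 2 cKO arrays well above background.

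For 7 further named genes the cKO signal was not well above background, so only a lower limit of the fall can be given. That limit sets the control mean against the lowest signal of any probe well above background on each cKO array, or the probe's own signal where that was higher. The fall was at least 6.72-fold for H2al1n and at least 4.96-fold for H2al1o, which like H2al1m lie on the X chromosome. It was at least 4.17-fold for Fam169b and at least 3.80-fold for Naip1, a sensor protein of the inflammasome, although matches of its probe to related gene copies were not searched. The limits were at least 2.81-fold for Upk1b (a uroplakin), 1.92-fold for Lcn12 (a lipocalin) and 1.42-fold for Isl2 (a LIM homeobox transcription factor). Their adjusted p ranged from 0.0121 for H2al1o to 0.0355 for Lcn12. In all, 12 of the 42 lower genes were not well above background in cKO skin.

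Of the rises, 7 genes fell under the rule for named genes. Slc5a1 was 2.85-fold higher in cKO skin, from -3.81 ± 0.04 to -2.30 ± 0.06 (SD, n = 2 each; adjusted p = 0.0276). Abhd14b was 2.36-fold higher (adjusted p = 0.0488), Agt 2.34-fold (adjusted p = 0.0428) and Isoc2a 2.06-fold (adjusted p = 0.0463). Ces2e, a carboxylesterase, Gadl1, an amino acid decarboxylase, and Aox3, an aldehyde oxidase, were not well above background in control skin. In the processed signal they rose at least 2.07-fold, 1.76-fold and 1.59-fold (adjusted p = 0.0324 each). All 3 lost their call with normexp without spots below their local background, as given below. All 20 of the genes named in these paragraphs as changed lost their call with the replicate block (adjusted p from 0.0567 to 0.0938) and without either control array. A total of 8 lost it without cKO replicate 1 and 9 without cKO replicate 2, among them 6 and 7 of the 7 named rises.

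**Figure D2:**
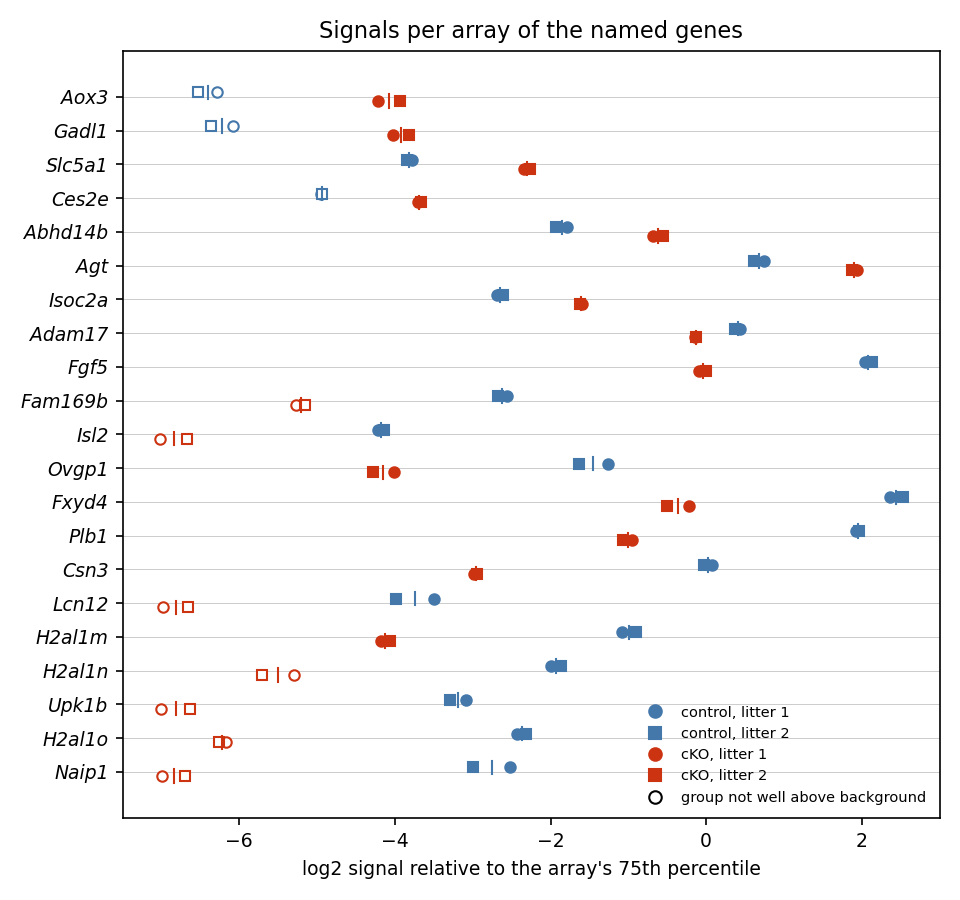
Log2 signal relative to the array's 75th percentile (horizontal axis) on each array for Adam17 and the 20 named genes that passed the test, ordered by their difference; circles are litter 1, squares litter 2, blue control, red cKO, vertical ticks the group means, and open symbols groups not well above background on either array. For Plb1 the control arrays lie near 1.95 and the cKO arrays near -1.01, and no gene shown has overlapping groups.

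Groups of genes were compared through 38 lists of pathways and cell types. By limma's camera test with a preset correlation of 0.01, 11 lists shifted against the other genes, 3 upward and 8 downward. With a correlation estimated from the 4 arrays, 0 lists passed (adjusted p between 0.670 and 0.754 for the 11; 1 list had an unadjusted p under 0.05). By limma's fry, which asks whether a list's genes move on balance one way, 0 lists passed and 10 had an unadjusted p under 0.05. Fry's mixed test, which asks whether a list's genes move in either direction, passed 20 lists at an adjusted p of 0.05. It does not bear on a shared shift, and fry elsewhere here means the directional test. With the replicate block, 14 lists passed camera's preset test, 6 upward and 8 downward. Of all members of the lists, Fgf5 was the only gene that passed the test over all genes.

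The genes of the hair follicle's hardened parts shifted downward. Of 39 measured hair shaft keratins and keratin-associated proteins, the structural proteins of the hair fibre, 31 were lower in both litters and 5 higher in both. The median difference was -0.23 (-0.24 in litter 1 and -0.22 in litter 2; camera adjusted p = 7.5e-07, and adjusted p = 0.670 with an estimated correlation). Adjusted over the list alone, 4 members were lower and 1 was higher. Krtap4-7 differed by -0.98 ± 0.10 (SE; adjusted p = 0.0545 over all genes), while Krt36 stood at 0.998 ± 0.11 (adjusted p = 0.0635). Of 14 genes of the inner root sheath and companion layer, which surround the growing hair, 10 were lower in both litters, with a median of -0.25 (camera adjusted p = 0.0012, and adjusted p = 0.670 with an estimated correlation). Adjusted over the list alone, 5 were lower. Krt26 measured -0.93 ± 0.09 (adjusted p = 0.0534) and Krt27 -0.63 ± 0.08 (adjusted p = 0.0854). Skeletal muscle and fat genes, described below, were higher in the same biopsies.

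The other lists of the hair follicle and its glands did not pass. The list of hair matrix and follicle regulators held Fgf5 but had a median of -0.0021 over 25 genes (adjusted p = 0.669). Bulge and follicle stem cell genes had a median of -0.07 (adjusted p = 0.273), with Fgf22 at -0.73 ± 0.11 (adjusted p = 0.114). Sebaceous gland genes had a median of -0.08 (adjusted p = 0.273), with Soat1 at -0.56 ± 0.16. Melanocyte genes had a median of 0.30 (adjusted p = 0.0825; 0.0413 with the replicate block), with Pmel at 0.48 ± 0.15 and Mitf at -0.59 ± 0.12.

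A list of genes known to respond to signalling from the EGF receptor through MAP kinase, immediate-early genes among them, shifted downward. Of 24 measured, 14 were lower and 3 higher in both litters, with a median of -0.10 (camera adjusted p = 0.0064, and adjusted p = 0.670 with an estimated correlation; 0.0515 without control replicate 2). Adjusted over the list alone, 3 were lower and 1 was higher. Egr1, an immediate-early transcription factor gene, stood at -2.31 ± 0.20 (adjusted p = 0.0513), and Dusp6, a phosphatase that restrains ERK, at -1.03 ± 0.10 (adjusted p = 0.0534). The list's mean was -0.25. Egr1 and Junb also belong to the immediate-early and heat-shock list, which did not pass (median -0.05, camera adjusted p = 0.273). Whether the shift reflects signalling from the EGF receptor was not tested. The EGF receptor's ligands and receptors had a median of 0.08 and a mean of -0.04 over 10 genes (camera direction down, adjusted p = 0.932), with Tgfa at -0.54 ± 0.13 and Egf at 0.34 ± 0.09. Known ADAM17 substrates, which include some of these ligands and a receptor, had a median of 0.08 over 30 genes (adjusted p = 0.932), with Cx3cl1 at 0.78 ± 0.08 (adjusted p = 0.0628) and Sdc1 at -0.51 ± 0.10. The ADAM family and ADAM17 regulators had a median of 0.10 (adjusted p = 0.211), with Adam8 at 0.98 ± 0.09 (adjusted p = 0.0534). Notch pathway genes had a median of 2.56e-05 (adjusted p = 0.971), with Heyl at -0.69 ± 0.12 and Jag1 at 0.47 ± 0.11.

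In the epidermis, basal keratinocyte genes shifted upward. Of 17 measured, 13 were higher in both litters, with a median of 0.19 (camera adjusted p = 0.0257, and adjusted p = 0.670 with an estimated correlation), and 0 members passed when adjusted over the list alone. The call was lost without control replicate 1 (adjusted p = 0.0733) and without cKO replicate 1 (adjusted p = 0.0762). Genes for the lipids of the skin barrier shifted downward, with 16 of 27 lower in both litters and a median of -0.23 (camera adjusted p = 0.0018, and adjusted p = 0.670 with an estimated correlation). Of these, Lipk measured -0.58 ± 0.09 and Aloxe3 0.59 ± 0.12, and 0 passed over the list alone. Tight and gap junction genes shifted downward with a median of -0.13 over 19 genes (camera adjusted p = 0.0257, and adjusted p = 0.754 with an estimated correlation), with Gjb2 at -0.57 ± 0.10. That call was lost without control replicate 2 (adjusted p = 0.259) and without cKO replicate 1 (adjusted p = 0.209).

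The differentiated layers of the epidermis held larger single differences that went both ways. Of 37 cornified envelope and granular layer genes, 18 were higher and 5 lower when adjusted over the list alone, and 0 passed over all genes. The list's median was 0.31 (0.06 in litter 1 and 0.42 in litter 2; camera adjusted p = 0.0763). Lce3c was among the lower ones, at -2.91 ± 0.29 (adjusted p = 0.0571), as was Padi1, a peptidylarginine deiminase, at -0.99 ± 0.10 (adjusted p = 0.0628). Spinous and suprabasal genes had a median of 0.09 (adjusted p = 0.0640), with Krt1 at 1.74 ± 0.30 (adjusted p = 0.127) and Krt2 at 0.78 ± 0.14. The small proline-rich proteins differed in sign by measure, with a mean of 0.26, a median of -0.28 and a downward camera test over 12 genes (adjusted p = 0.0825). Sprr2d, not well above background in control skin, measured at least 7.12-fold higher in cKO skin (adjusted p = 0.117). Stress keratins and wound-type genes had a median of 0.24 (adjusted p = 0.273), with the interleukin 36 gene Il1f6 at 2.31 ± 0.22 (adjusted p = 0.0534) and Krt6a at 0.80 ± 0.13 (adjusted p = 0.115). Epidermal proteases and their inhibitors had a median of 0.30 (adjusted p = 0.0806), with Klk8 at 0.92 ± 0.15.

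**Figure D3:**
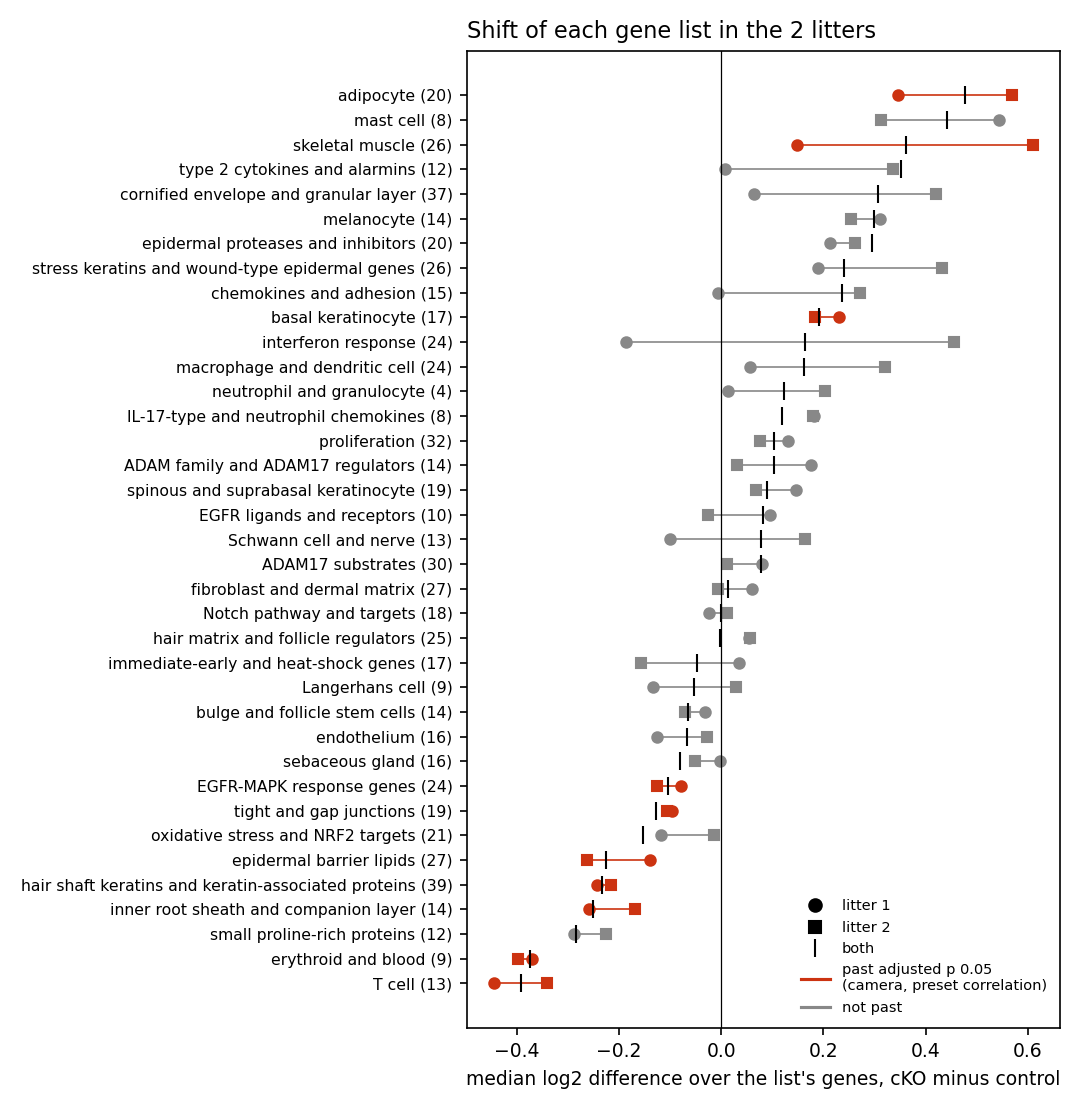
Median log2 difference between cKO and control skin (horizontal axis) over the genes of each list, in litter 1 (circles), litter 2 (squares) and both (ticks), with the number of measured genes in parentheses and the sex-linked list left out; red marks lists past an adjusted p of 0.05 by camera with the preset correlation. Hair shaft genes lie at -0.24 and -0.22 in the litters and fat genes at 0.35 and 0.57, and with an estimated correlation 0 lists passed.

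Genes of tissues other than the epidermis also differed. Fat cell genes shifted upward, with 15 of 20 higher in both litters and a median of 0.48 (0.35 in litter 1 and 0.57 in litter 2; camera adjusted p = 7.4e-05, and adjusted p = 0.670 with an estimated correlation). Adjusted over the list alone, 7 were higher, led by Retn (resistin) at 1.68 ± 0.15 and Thrsp, a lipogenic gene, at 0.89 ± 0.08 (adjusted p = 0.0534 over all genes for both). Skeletal muscle genes shifted upward, with 19 of 26 higher in both litters and a median of 0.36, but 0.15 in litter 1 against 0.61 in litter 2 (camera adjusted p = 5.5e-05, and adjusted p = 0.754 with an estimated correlation). Mb (myoglobin) measured 0.84 ± 0.10. Red cell genes shifted downward, with all 9 lower in both litters and a median of -0.37 (camera adjusted p = 0.0018, and adjusted p = 0.704 with an estimated correlation; 0.0620 without cKO replicate 2). The estimated correlation of the red cell list was 0.32, against the preset 0.01. Slc4a1, the red cell anion exchanger, measured -0.92 ± 0.09 (adjusted p = 0.0582). Fibroblast and dermal matrix genes had a median of 0.01 and a mean of -0.0018 (camera direction up, adjusted p = 0.932), endothelial genes a median of -0.07 (adjusted p = 0.167) and Schwann cell and nerve genes a median of 0.08 (adjusted p = 0.971).

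Among immune cells, T cell genes shifted downward. Of 13 measured, 8 were lower and 1 higher in both litters, with a median of -0.39 (camera adjusted p = 8.6e-04, and adjusted p = 0.670 with an estimated correlation), or -0.36 with the member below background set to its limit. Adjusted over the list alone, 6 were lower, among them Cd3g at -0.76 ± 0.13 and Itgae, an integrin of epidermal T cells, at -0.59 ± 0.10 (adjusted p = 0.123 over all genes for both). Mast cell genes had a median of 0.44 (adjusted p = 0.0825; 0.0040 with the replicate block), and macrophage and dendritic cell genes a median of 0.16 (adjusted p = 0.0923), with Ccl2 at 1.002 ± 0.22. Langerhans cell genes had a median of -0.05 and a mean of 0.02 (camera direction down, adjusted p = 0.932). Only 4 neutrophil genes were measured, with a median of 0.12 and a downward camera test (adjusted p = 0.932). Medians were 0.12 for IL-17-type and neutrophil chemokines (adjusted p = 0.0825), with Ccl20 at 0.88 ± 0.10. They were 0.24 for chemokines and adhesion (adjusted p = 0.211), 0.35 for type 2 cytokines and alarmins (adjusted p = 0.273) and 0.16 for interferon response genes, which stood at -0.19 in litter 1 and 0.46 in litter 2 (adjusted p = 0.374).

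Of the lists on growth and stress, proliferation genes had a median of 0.10 with 17 of 32 higher in both litters (adjusted p = 0.0876; 0.0461 with the replicate block). Immediate-early and heat-shock genes had a median of -0.05 (adjusted p = 0.273), with Egr1 at -2.31 ± 0.20 and Junb at -0.42 ± 0.10. Oxidative stress and NRF2 target genes had a median of -0.15 (adjusted p = 0.339). Adjusted over the list alone, 5 of its members were higher and 5 lower, among them Slc7a11, the cystine transporter, at -1.95 ± 0.20 (adjusted p = 0.0592) and Mt1 at 0.79 ± 0.09 (adjusted p = 0.0689).

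Sex-linked genes separated 1 animal from the other 3. In cKO replicate 2, the Y-linked gene Eif2s3y measured -6.44 against values of 2.06 to 2.17 on the other arrays, and Xist, the X-inactivation transcript, measured 2.37 on its brightest probe against -6.55 or less elsewhere. The sex-linked list of 5 measured genes was therefore lower in litter 2 (median -4.65) and not in litter 1 (0.00024; camera adjusted p = 0.0257, and adjusted p = 0.754 with an estimated correlation; 0.734 without cKO replicate 2). Of the 53 genes that passed between the genotypes, 4 lie on the X or Y chromosome. With the X and Y chromosomes left out, a choice made after the data were examined, 48 genes passed, 10 higher and 38 lower.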

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

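The fits without the X and Y chromosomes and the normexp fit without spots below their local background were chosen after the data were examined; the other alternatives were planned. The 53 calls (11 higher, 42 lower) kept their direction in all alternative fits that tested them, except in 9 with normexp on all spots and in 1 with probes averaged, but their number depended on the processing. It was 80 with quantile normalization (23 higher; all 53 remained), rounded, 1.1e+02 with median centring (exactly 30 higher and 77 lower; all 53 remained), 193 with an intensity trend in the prior (49 and 144; 51 remained), and 28 with probes well above background on all arrays (5 and 23), where 34 of the 53 were tested. Without a filter on dim probes 28023 genes entered and 0 passed in any direction. With normexp on all spots 0 passed, where cKO replicate 2 had the distorted background fit. Without the 3 spots behind it 134 passed (35 and 99), of which 40 were among the 53. Of the 20 named genes that passed, 16 kept their call there. Ces2e, Gadl1, Aox3 and Isl2 lost it, at log2 differences of 0.39, 0.45, 0.64 and -0.54 (adjusted p = 0.143, 0.104, 0.0595 and 0.0886, limma). The lower limits given for Ces2e, Gadl1 and Aox3 thus hold for the processed signal only. At an adjusted p of 0.1, 251 passed (82 and 169). A difference of 2-fold in both litters, without a test, held for 152 genes (44 and 108), and 35 probes passed when each was tested by itself (6 higher). With the replicate block 0 genes passed, 0 of them higher and 0 lower. In this balanced design the block, like the intensity trend and the robust prior, cannot alter an estimate. All 53 thus kept their direction there by construction, and Adam17 stayed at -0.54. It missed the threshold in all alternatives, between -0.57 and -0.44, with adjusted p from 0.0715 to 0.728. Leaving out 1 array gave 0 to 38 genes, 0 to 9 of them higher and 0 to 29 lower, and left a single animal in a group, which was assumed to vary like the other pair. The self-test did make calls with 2 arrays per group. Apart from the filter, the prior, the number of arrays and those 3 spots, the cause was not tested.

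The number of lists that passed was 11, and 10 to 14 in the normalization, prior, flag, probe, block and sex chromosome alternatives. It was 19 without the filter, where the sex-linked list no longer passed (mean -0.78, adjusted p = 0.0530), 0 with an estimated correlation, 0 with fry, and 14 to 17 with 1 array left out (17 without control replicate 1). With normexp on all spots the mean of the basal keratinocyte list turned to -0.0531 (adjusted p = 0.410), that of the T cell list to 0.27 (0.384), Lcn12 to 0.37 (0.852) and Isl2 to 0.51 (0.80). The fat, skeletal muscle and sex-linked lists also lost their calls there, at means of 0.24 (adjusted p = 0.0816), 0.12 (0.386) and -0.14 (0.929), against 0.43, 0.34 and -2.38. Without those 3 spots none of the 4 turned, and the fat and muscle lists passed at 0.40 and 0.33. The fibroblast list, at a mean of -0.0018 with all arrays, passed at -0.24 without cKO replicate 1 (adjusted p = 0.0315), and passed at 0.21 without control replicate 1 and at 0.24 without cKO replicate 2. Macrophage and dendritic cell genes passed at 0.52 without control replicate 1 (adjusted p = 1.7e-08) and interferon response genes at 0.52 without cKO replicate 1 (adjusted p = 2.3e-05). No slide block was run, as there was 1 slide. Between 53.7% and 56.6% of spots were well above background, so falls to or rises from background have only lower limits.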

Other observations

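Several genes past the threshold lay outside the rule for named genes and are given here after their values were seen. Trpv6, an epithelial calcium channel, was 5.03-fold lower in cKO skin (adjusted p = 0.0148), Mab21l4 4.77-fold lower (adjusted p = 0.0178) and Dio3, a deiodinase that inactivates thyroid hormone, 5.26-fold lower (adjusted p = 0.0355). Clu (clusterin) and Ctse (cathepsin E) were 2.29-fold and 3.11-fold lower (adjusted p = 0.0419 and 0.0428). Vnn1, a pantetheinase, was 2.69-fold lower (adjusted p = 0.0457). Npr2, a natriuretic peptide receptor, was 3.92-fold lower on its brightest probe (adjusted p = 0.0324), but its other probes differed by -0.0016 and -0.16. Of the genes past the threshold, the largest rise was at a probe without a gene name, NAP000011-006 on chromosome 6 (39140786, mm9), which was 28.5-fold higher (adjusted p = 0.0236). With the replicate block none of these passed.

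Some large differences stopped short of the threshold. Hp (haptoglobin) stood at 1.37 ± 0.12, and the acute-phase gene Saa3, not well above background in control skin, was at least 4.96-fold higher (adjusted p = 0.0534 for both). Apoe, one of the brightest signals here at 8.53 in control skin, stood at -1.32 ± 0.12 (adjusted p = 0.0534). In 17 genes outside the X and Y chromosomes, 1 array lay at least 2 log2 units from the other 3, which spanned no more than 1 unit. For Taf3 the gap was 9.76 and for Tyro3 5.58, both high in cKO replicate 2. Serpina3b on chromosome 12 was low in control replicate 2 by 3.51.

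The 3 patterns below were found in the results. The tests of chance placement, of a lower share of keratinocytes and of the sex of cKO replicate 2 were chosen after the values they measure were seen, and the other 3 tests after the patterns but before their own outcome. Around Fgf5, 5 of the 16 genes tested within 1.5 Mb had an adjusted p under 0.1, all lower in cKO skin. They were A730035I17Rik (-2.44), Prdm8 (-0.84), Fgf5 (-2.13), Cfap299 (at least 4.21-fold lower, not well above background in cKO skin) and Prkg2 (-0.90), between 98612147 and 99372439 on chromosome 5 (mm9). A change of the whole segment was argued against, only weakly, by Bmp3 and D630004D15Rik. These lie among them and differed by 0.11 ± 0.21 and -0.08 ± 0.28 (SE; smallest size 0.078). With 2 arrays per group these errors are wide and do not rule out a shift of moderate size. The 2 probes also lie close together, starting at 99308890 and 99312427, so they may not count as separate evidence. Chance placement was argued against by random sets of as many genes as were lower at an adjusted p under 0.1. These sets drew each gene independently, so close neighbours count separately, such as A730035I17Rik and Prdm8, whose probes start 4079 bases apart. The shares below may therefore be too small. A neighbourhood of 1.5 Mb to each side as crowded as that of Fgf5, with 4 of the 15 other genes lower, arose anywhere in the genome in a share of 0.00040 of 10000 sets, and in 0.00020 without keratin and cornified envelope families. Over the whole genome, genes with an adjusted p under 0.1 made 74 pairs within 1 Mb, against 52.5 in random sets (share with as many 0.0149), and without these families 44, against 46.5 (share 0.625), so apart from them the result covers the neighbourhood of Fgf5 only. Regulation shared by these genes and alleles of the 129Sv and C57BL/6 strains were not tested and stay open.

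Fat and muscle lists were higher in cKO skin, together with the basal keratinocyte list. A lower share of keratinocytes would raise all other tissues alike. Against it for the fat list, that list's median exceeded that of the pooled fibroblast, endothelial and Schwann cell lists by 0.42 in litter 1 and 0.57 in litter 2, narrowly more than the SD over the fat list's members (0.36 and 0.54). The muscle list's median exceeded it by 0.22 and 0.61, which in litter 1 lay within the SD over its members (0.29), so for muscle this stays open, although basal keratinocyte genes had a median of 0.19. More fat and muscle tissue in the biopsies would raise their abundant transcripts alike. Of 5 such genes each, 4 fat genes (Adipoq, Cfd, Lpl and Car3, not Fabp4) and 4 muscle genes (not Ckm) were higher in both litters. Their medians were 0.47 and 0.58 for fat and 0.14 and 0.65 for muscle. All of these genes are members of the fat and muscle lists, so their rise largely repeats the pattern and is not separate evidence. A larger share of deep tissue and a change within fat and muscle cells cannot be told apart here, since Fabp4 stayed near 0 (-0.08 and 0.08 in the litters) and Ckm was lower in litter 1 (-0.12) and higher in litter 2 (0.30), and both may contribute.

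The 3 H2al1 genes on the X chromosome were lower in cKO skin. The different sex of cKO replicate 2 would leave litter 1 near 0. The median there was -2.87 with the cKO signals of H2al1n and H2al1o, which were below background, set to their limits. H2al1m, which was above background, differed by -3.09 there, and H2al2a on chromosome 2 was 3.68-fold lower (adjusted p = 0.0214, limma). These genes were taken up because they passed the test over all 4 arrays, which all but fixes a fall in both litters. The values show a fall in litter 1, where both animals had Y-linked signal, but are not a separate test of sex. Probes for the same stretch of near-identical genes would be similar, yet these shared from 38.9% to 47.6% of bases in their best ungapped overlap. This cannot decide whether they read a single signal, as probes at different places of near-identical transcripts need not be similar. Matches of each probe to the other genes' transcripts were not searched. Probes that each match further copies in the genome, and alleles of the 129Sv and C57BL/6 strains that differ between the animals, were not tested and stay open, as does an effect of ADAM17 loss itself.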
